A study of Mus musculus with 2 samples.

How the data were processed

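Total RNA was sequenced from the pancreas of mouse embryos at embryonic day 12.5, with 1 library per genotype. The control library came from a pool of 6 pancreatic buds and the mutant library from a pool of 12. The mutant embryos carried floxed alleles of Gata4 and Gata6, 2 zinc finger transcription factors, together with a Cre recombinase driven from the Pdx1 promoter, which is active in the pancreatic epithelium and not in the mesenchyme around it. Per the labels' protocols, the whole pancreas was dissected, the RNA integrity number was above 8, the libraries were made with an Illumina TruSeq RNA kit. No sorting of cells is described there, so each value can sum over epithelium, mesenchyme, vessels, blood and nerve precursors.

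Per the labels, alignment used TopHat 2.0.4 and the mouse build mm9, with 4 mismatches and up to 10 hits allowed per read, and placed over 20000000 reads. The submitters' processing notes also name CASAVA 1.8.2, Cufflinks and DESeq, the last 2 without a version. Whether counting used the strand of the reads, and the transcript annotation, are not given in the sources used here. Reads with several hits were allowed, so genes with near-identical copies can share reads.

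The deposited data were 1 table of 250 genes whose column names are those of Cuffdiff, the testing program of Cufflinks. The authors deposited for each gene an FPKM value per library, that is fragments scaled by transcript length and by the number of mapped fragments. How the libraries were scaled against each other is not given in the sources used here. The table also holds the authors' deposited log2 fold change, a test statistic (a score whose sign is opposite to the fold change), and a p-value and q-value. The deposited log2 fold change differed from the log2 ratio of the FPKM values by rounding only, so it carries no pseudocount. Per the labels, the calls were made with DESeq, while the table has Cuffdiff's columns. Which program made the q-values is therefore open. With 1 library per genotype, those q-values compare 2 libraries and hold no measure of the variation between embryos.

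All 250 rows were marked significant by the authors, and the highest q in the authors' deposited table was 0.0496. Multiplying each q by the rank of its p and dividing by p gave a median of 14984 tests over the 96 genes with a p above 1e-04 (range 14837 to 14984), so the table holds 1.67% of the genes the authors tested. Genes outside the table either were not tested or did not pass, and their values were not analysed here. A true or false mark in the table was checked on every row. It was true for the 153 genes with both FPKM values of at least 1.01 and false for the 97 genes whose smaller value was 0.965 or less.

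Gene positions are those of the table, converted to a 1-based start, on mm9. They were compared with GENCODE vM1, which annotates the same build under its name NCBIM37, and 248 of the 250 rows were matched by overlap together with the symbol or, in 1 row, a date in its place. The start of 103 rows and the end of 119 rows were the same as in that annotation. The locus of the row with the date is that of Sept3. Another row joins Serpina3f and Serpina3g. In 34 rows the locus overlaps another protein-coding gene.

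For each gene, log2((mutant FPKM + 1)/(control FPKM + 1)) was computed, which understates the change of genes with low values. No test was run, because 1 library per group leaves no replicate spread, and differences are described by size. A gene was called higher or lower when this ratio was at least 1 in size, a change of 2-fold, and its FPKM was at least 1 in at least 1 library. The rule for naming genes took Gata4 and Gata6, the 10 highest and 10 lowest ratios, up to 4 members of each gene list, and 8 further fixed symbols where the table has them. Predicted genes were counted and not named. Some genes that the rule selects are not reported here by name and enter counts and medians alone. Further list members are named where they complete a list or are its exception, and these were chosen after their values were seen. The 27 gene lists covered pancreatic, gut and liver epithelium, signalling pathways, mesenchyme and the other cell types a dissected bud can hold. The naming rule, the lists and all alternatives not described as later additions were fixed before the data were examined. For a list with at least 5 members, the median ratio was placed among the medians of 10000 random lists of the same size, drawn from the table in 5 bins of mean expression. This percentile describes the list within a table of called genes and is not a test.

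The calculations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. They were tested on simulated data: in lists of 9 genes from the 238 passing the FPKM filter, 5 of 100 random lists fell outside the 2.5 to 97.5 percentiles, as did 35 of 100 lists made up of lower genes alone, on the low side. The percentile therefore often misses a list that is lower throughout. The number of tests was recovered as 14984 in tables simulated with that number.

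The depth of each library is not given in the sources used here. The lowest control values are of the size that single fragments give. Multiplied by transcript length, the control values of 10 single-transcript genes under 0.2 lay closest to whole multiples of 0.0294 FPKM times kilobases, the candidate value of 1 fragment. The range searched and the limit of 0.2 were set after the low values had been seen. As many as 6.5% of 1000 random sets of values lay as close, so this step is tentative, and no counting intervals are given. The mutant library had 1 such gene, and its step was not estimated. Alternatives were a pseudocount of 0.1 or 5, centring on the median ratio, the authors' deposited log2 fold change, FPKM minimums of 0 and 5, thresholds of 1.5-fold and 4-fold, q limits of 0.05 and 0.01, and removal of small RNA genes. A minimum of 1 FPKM in both libraries was added after seeing the data. Leaving out a replicate was not possible.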

Results

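RNA sequencing compared the pancreas of control mouse embryos with that of embryos lacking Gata4 and Gata6 in the Pdx1 lineage, at the early bud stage, when the buds consist of proliferating progenitors and the first differentiated cells. The comparison asks which genes differ in expression when both factors are lost during early pancreas formation. There was 1 pooled library per genotype, of 6 control and 12 mutant buds. No difference below has a replicate check, and no value has an error. The depth of each library is unknown beyond the more than 20000000 mapped reads given in the labels. Across the 250 genes of the authors' deposited table, FPKM ranged from 0.00972 to 612.

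Among the genes the table holds, the acinar, endocrine and immune genes were lower in the mutant library. The hedgehog, neural and skeletal muscle genes were higher, as were most of the intestine and mesenchyme genes. Most members of each list are outside the table. By the rule of size, 113 of the 250 genes were lower in the mutant and 121 were higher. Of the other 16 genes, 12 were under 1 FPKM in both libraries and 4 changed by less than 2-fold on the log2(FPKM + 1) scale. When the ratios were centred on 1.11, the median of the genes that passed the FPKM minimum, the split was 114 lower against 38 higher. That median comes from a table chosen for change. Subtracting a positive value can only remove higher genes and add lower ones. The centred split therefore does not show the balance among all the genes tested. By the plain ratio of FPKM, 24 genes were at least 10-fold lower and 46 at least 10-fold higher. The smallest change in the authors' deposited table was 1.22 on the log2 scale.

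**Figure D1:**
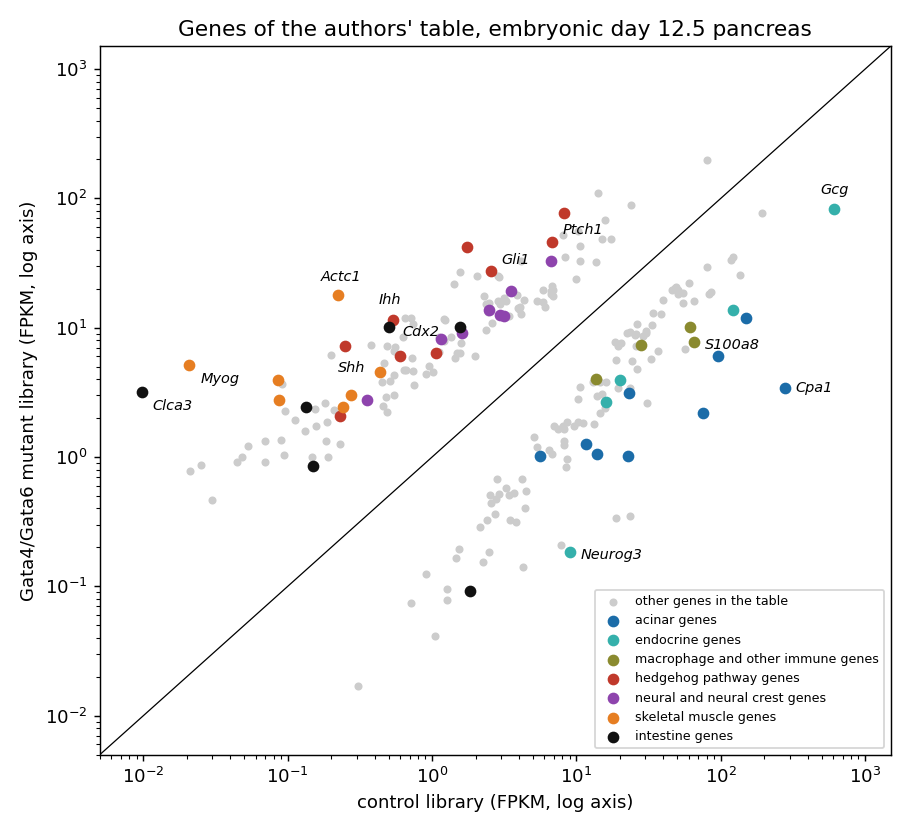
FPKM of each gene of the authors' table in the control library (horizontal, log axis) and in the Gata4/Gata6 mutant library (vertical, log axis), 1 point per gene and 1 library per genotype, with members of 7 gene lists coloured and the line marking equal values. All 9 acinar and all 5 endocrine genes lie below the line, and all 9 hedgehog, 8 neural and 7 skeletal muscle genes lie above it.

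Neither Gata4 nor Gata6 is among the 250 genes, so the table gives no value for the targeted genes and the genotype labels could not be checked against them. Among the relatives and partners of these factors, Gata3 was the only one of 9 annotated genes in the table, at 0.546 FPKM in the control and 4.31 in the mutant, and it did not pass the rule with a pseudocount of 5, with centring, with a minimum of 5 FPKM or with 1 FPKM required in both libraries, the last of these chosen after seeing the data. Pdx1 and Ptf1a, which mark the pancreatic progenitor epithelium, and the foregut factor Sox2 are likewise outside the table.

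Acinar genes, which encode the digestive enzymes and their partners, were lower in the mutant in all 9 cases in the table, out of 49 annotated members of the list. Cpa1, a carboxypeptidase that also marks the tip progenitors of the early bud (mm9 chromosome 6, 30589221 to 30595361), stood at 277 FPKM in the control and 3.39 in the mutant, the lowest ratio of any gene, at −5.98 on the log2(FPKM + 1) scale. Colipase, Clps, was 75.4 against 2.18 FPKM. Serpina6, a serum corticosteroid carrier, was 150.4 against 11.9. The lipase relative Pnliprp1 was 22.7 against 1.02. Cela1, Ctrb1, Cckar and Cel were also lower. The median ratio of the list was −3.55, below all of the 10000 random lists, and it ran from −4.67 to −2.20 over the alternative pseudocounts, scalings and minimums. Adding the 9 genes together, acinar FPKM was 675 in the control and 30.9 in the mutant.

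Endocrine genes were lower in all 5 cases in the table, out of 59 annotated members. Neurog3, the transcription factor that commits progenitors to endocrine fate (chromosome 10, 61595838 to 61597511), was 9.06 FPKM in the control and 0.186 in the mutant, a ratio of −3.08 on the log2(FPKM + 1) scale. With so low a mutant value the ratio depends on the pseudocount, at −1.44 with 5 and larger in size than −3.08 with 0.1, and Neurog3 did not pass with 1 FPKM required in both libraries, where 4 of the 5 genes did. The hormone genes Pyy and Gcg, which encode peptide YY and glucagon, were 121 against 13.7 and 612 against 83.2 FPKM. Nkx2-2, a transcription factor of endocrine cells, was 15.9 against 2.64, and the granule protein gene Chga was lower as well. The median ratio was −2.86, at percentile 0.355 of the random lists, and ran from −3.98 to −1.48 over the alternatives. The table places Nkx2-2 in a locus of 154 kb, where the annotated gene spans 16.7 kb, and the Neurog3 locus overlaps another coding gene.

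The list of pancreatic epithelial transcription factors was split, with 4 of 24 annotated members in the table. Nkx2-2 and Prox1 were lower, Prox1 at 10.2 against 2.81 FPKM. Foxa1, a forkhead factor of the whole gut endoderm, was 0.711 in the control and 12.0 in the mutant, and Onecut2 was 1.12 against 8.51. Of the 2 lower genes 1 passed the rule with a pseudocount of 5, and of the 2 higher genes 1 did with 1 FPKM required in both libraries. In the ductal list, 2 of 21 genes were present. The matrix protein gene Spp1 was 148 against 12.1 FPKM and the tetraspanin gene Tspan8 was 2.94 against 15.2, and Tspan8 did not pass the rule after centring.

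Hedgehog pathway genes were higher in all 9 cases in the table, the largest share of any list with at least 5 members in the table, at 42.9% of 21 annotated genes. Both secreted ligands of the gut, Shh and Ihh, were included. Shh was 0.248 FPKM in the control and 7.17 in the mutant, and Ihh was 0.533 against 11.5. The receptor gene Ptch1, itself a transcriptional readout of the pathway, was 6.76 against 46.3, the transcription factor Gli1 (chromosome 10, 126760783 to 126778635) was 2.55 against 27.4, and the antagonist Hhip was 1.06 against 6.37. The forkhead genes Foxf1a, Foxf2 and Foxl1 of gut mesenchyme are also on the list, with Foxf1a at 8.17 against 76.6 FPKM and Foxf2 (chromosome 13, 31717685 to 31723275) at 1.73 against 42.0, the highest ratio of any gene at 3.98 on the log2(FPKM + 1) scale. The median ratio was 2.71, above all of the random lists, and ran from 1.58 to 3.33 over the alternatives. In the authors' deposited table, q was 3.54e-09 for Ptch1, 3.69e-08 for Gli1 and 1.53e-08 for Shh. With 1 FPKM required in both libraries, 5 of the 9 genes passed the rule. The Shh locus of the table spans 262 kb, where the annotated gene spans 10.3 kb, and the Gli1 locus overlaps Arhgap9.

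**Figure D2:**
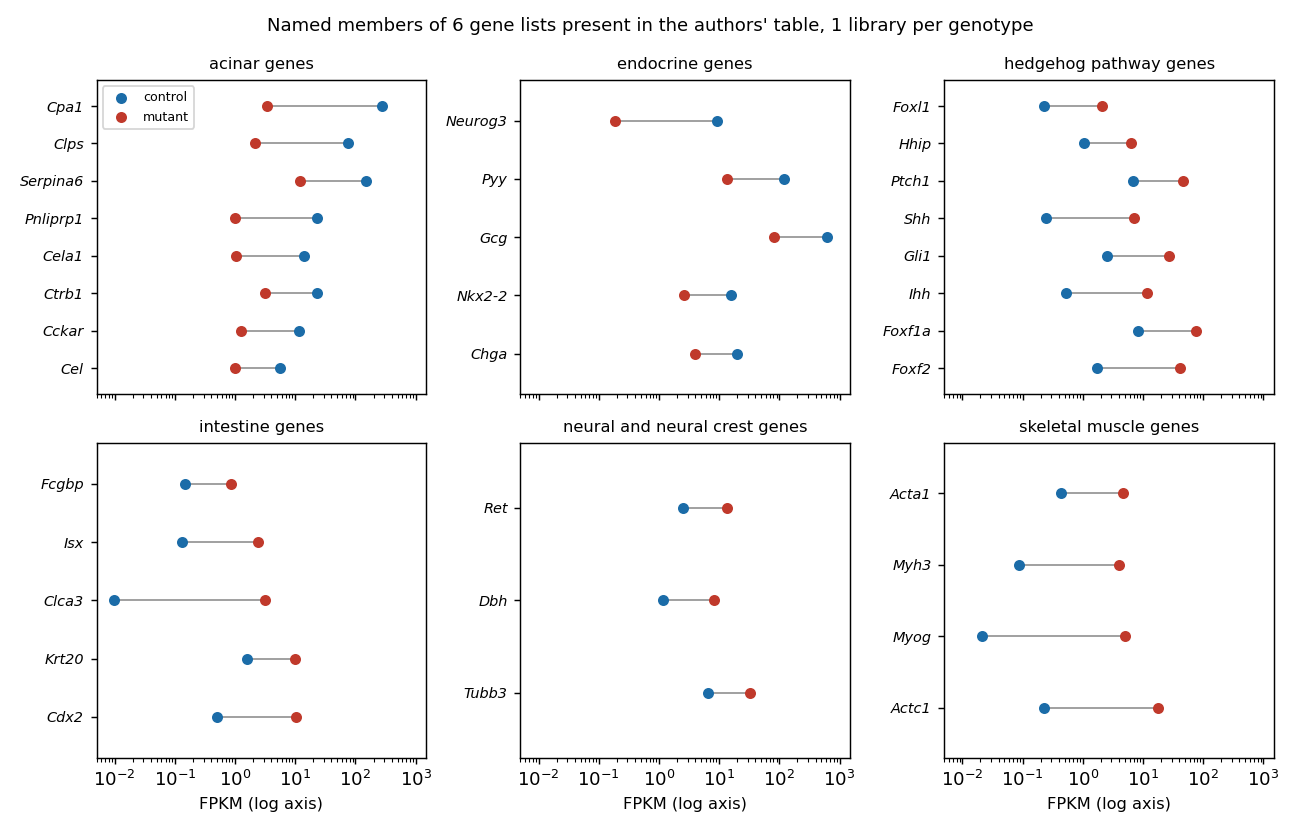
FPKM (log axis) in the control library (blue) and the mutant library (red) for the named members of 6 gene lists that the table holds, with 1 library per genotype and a line joining the 2 values of a gene. Acinar and endocrine genes run from higher blue to lower red points, and hedgehog, neural and skeletal muscle genes run the other way, as do the intestine genes drawn, while the 1 intestine gene that was lower is not drawn.

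Gut epithelial genes were mostly higher, although few of each list were present. In the intestine list, 6 of 61 annotated genes were in the table, of which 4 were higher, 1 was lower and 1, Fcgbp, stayed under 1 FPKM in both libraries. Cdx2, the homeobox factor of intestinal identity (chromosome 5, 148112476 to 148118825), was 0.506 FPKM in the control and 10.2 in the mutant. Krt20, a keratin of mature gut epithelium, was 1.55 against 10.0, and the intestinal homeobox gene Isx was 0.134 against 2.43. The goblet cell gene Clca3 was 0.00972 against 3.18. Its control value corresponds to 0.971 fragments at the tentative value of 1 fragment, so no fold is given. Clca3 is among the genes from which that value was estimated, so the figure is no independent check of it. The median ratio was 2.05, at percentile 97.7, and ran from 0.71 to 4.18 over the alternatives. Of the 4 higher genes, 1 passed the rule with centring or with 1 FPKM required in both libraries, and 2 did with a pseudocount of 5 or a minimum of 5 FPKM. In the stomach list, 2 of 41 genes were present and both were higher. The antral factor Nkx6-3 was 0.379 against 7.35 and Foxq1 was 0.0918 against 3.69. Of these 2 genes, 1 passed the rule with a pseudocount of 5, with centring or with a minimum of 5 FPKM, and 0 did with 1 FPKM required in both libraries.

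Of the 50 annotated liver and bile duct genes, 4 were in the table, with 3 lower and 1 higher. Alb was 54.9 FPKM in the control and 15.6 in the mutant, Apoe was 194 against 76.7 and Trf was 47.9 against 20.3. Tdo2, a tryptophan-degrading enzyme, was 0.484 against 7.24, and did not pass with 1 FPKM required in both libraries. Colec10, a collectin on none of the lists and among the 10 highest ratios, was 2.05 against 25.1.

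The mesenchyme list divided into 8 higher and 3 lower genes, out of 52 annotated, with a median ratio of 1.96 at percentile 97.8, which ran from 0.84 to 2.69 over the alternatives. The 8 include Foxf1a and Foxf2, which are also counted in the hedgehog list, so the results of these lists are not separate. After centring 4 of the 8 passed the rule, and with 1 FPKM required in both libraries 1 of the 3 did. Among its genes of contractile proteins, Acta2, Actg2, Cnn1 and Myh11 were higher and Des was lower. Six2, a homeobox factor of the mesenchyme at the gastric outlet, was 1.42 FPKM in the control and 21.6 in the mutant. The genes that were lower include Tlx1, the factor required to form the spleen (chromosome 19, 45225205 to 45231433), at 23.4 against 0.353, and Prrx1. In the spleen primordium list, Tlx1 and Wt1 were the 2 genes present of 11 annotated, and 1 of them passed the rule with 1 FPKM required in both libraries. Wt1, which also marks the mesothelium, was 26.2 against 4.79. Of the mesothelium list, Wt1, Aldh1a2 and Msln were present of 14 genes, with Msln under 1 FPKM in both libraries at 0.0695 and 0.920. Kazald1, which lies near Tlx1 on chromosome 19 and is on no list, was 18.7 against 0.338.

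Signalling genes outside the hedgehog list were higher in 5 of 6 cases. Aldh1a2, which makes retinoic acid in mesenchyme, was 14.1 FPKM in the control and 110.9 in the mutant. The growth factor gene Fgf10 was 2.86 against 16.1, the Fgf-responsive factor Etv4 was 6.79 against 21.0 and the Bmp antagonist Grem1 was 0.649 against 11.9. In the Wnt list, the antagonist Sfrp5 was 2.30 against 17.5 and the ligand Wnt5a was 15.7 against 2.39. None of the 20 Notch pathway genes was in the table.

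Neural and neural crest genes were higher in all 8 cases in the table, out of 27 annotated. Ret, a receptor of enteric neural crest, was 2.49 against 13.8 FPKM. The neuronal tubulin gene Tubb3 was 6.62 against 32.8, and Dbh, which makes noradrenaline, was 1.15 against 8.17. The median ratio was 2.03, at percentile 96.3, and ran from 0.91 to 2.46 over the alternatives. After centring, 2 of the 8 genes passed the rule. Gdnf, the ligand of Ret, which was on the list of kidney, adrenal and gonad genes, was 3.43 against 12.2. Six2 on that list of 17 genes was also higher, and 1 of these 2 genes passed the rule after centring.

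Skeletal muscle genes were higher in all 7 cases in the table, out of 18 annotated, and all 7 were under 0.5 FPKM in the control. Actc1, the embryonic striated muscle actin (chromosome 2, 113873025 to 113878547), was 0.224 FPKM in the control and 17.8 in the mutant. The myogenic factor Myog was 0.0209 against 5.11, the myosin gene Myh3 was 0.0862 against 3.94 and the actin gene Acta1 was 0.433 against 4.58. The control value of Myog corresponds to 1.05 fragments at the same tentative value of 1 fragment, which was estimated from Myog among other genes. The median ratio was 1.96, at percentile 99.3, and ran from 0.81 to 4.97 over the alternatives. With centring 3 of the 7 genes passed the rule, with a pseudocount of 5 or a minimum of 5 FPKM 2 did, and with 1 FPKM required in both libraries 0 did.

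Immune genes were lower in all 4 cases in the table, out of 23 annotated. The neutrophil genes S100a8 and S100a9 were 65.1 against 7.74 and 61.4 against 10.1 FPKM, and the macrophage genes Lyz2 and Mrc1 were 28.1 against 7.35 and 13.7 against 3.98. Stfa1, a protease inhibitor that is on no list, was 30.9 against 2.61. The table holds no member of the endothelial (21 annotated genes), erythroid (23), sex-linked (8), immediate early and heat shock (26) or p53 and apoptosis (17) lists. Of 23 cell cycle genes, the inhibitor Cdkn2b alone was present, at 0.112 against 1.92 FPKM, and it did not pass the rule under the alternatives named for Gata3. Of the small RNA and related classes, Rmrp was present, at 56.4 against 6.83, and its locus overlaps the coding gene Ccdc107.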

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

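The direction of each called named gene was the same with centring. A pseudocount of 0.1 or 5 cannot change a direction by construction. The authors' deposited log2 fold change cannot either, because it is the log2 ratio of the same FPKM values. Msln, under 1 FPKM, turned from higher to lower with centring, at −0.27. Centring subtracts 1.11, the median of a table chosen for change, which need not be near the median of all 14984 tested genes. The 121 higher and 113 lower genes became 69 and 75 with a pseudocount of 5, and 50 and 37 at 4-fold. Centring left 38 higher, and a q of at most 0.01 left 66 lower. Requiring 1 FPKM in both libraries, chosen after seeing the data, left 70 higher. Counts were called close when within 1.5 times of each other. Low values limited the smaller lists. Of 4 higher intestine genes, 2 passed the rule with a pseudocount of 5, 2 with a minimum of 5 FPKM, 1 with centring and 1 with 1 FPKM in both libraries, and the 1 lower intestine gene fell to 0 under the first, second and last of these. Of the 7 higher skeletal muscle genes, 2 passed with a pseudocount of 5, 2 with a minimum of 5 FPKM, 3 with centring and 0 with 1 FPKM in both libraries. Centring left 4 of 8 higher mesenchyme genes and 2 of 8 higher neural genes, and 1 FPKM in both libraries left 5 of 9 hedgehog genes and 1 of 3 lower mesenchyme genes. Of the lists with fewer than 5 genes in the table, the 2 higher stomach genes became 1 with a pseudocount of 5, centring or a minimum of 5 FPKM, and 0 with 1 FPKM in both libraries. Gata3 and Cdkn2b, each the 1 higher gene of its list, passed under none of these 4. Centring left 0 of 1 higher ductal gene and 1 of 2 higher kidney, adrenal and gonad genes. A pseudocount of 5 left 1 of 2 lower pancreatic transcription factors, with Prox1 at −0.96. With 1 FPKM in both libraries, 1 of 2 higher pancreatic transcription factors, 0 of 1 higher liver gene and 1 of 2 lower spleen genes passed. The counts of lower acinar and lower endocrine genes stayed between 8 and 9 and between 4 and 5 under the alternatives run. The median ratio of each of the 7 lists kept its sign under the alternatives run and moved in size. It came closest to 0 with a pseudocount of 5 in the acinar (−2.20), endocrine (−1.48), hedgehog (1.58), intestine (0.71) and skeletal muscle (0.81) lists, and with centring in the mesenchyme (0.84) and neural (0.91) lists. It was farthest from 0 with centring in the acinar (−4.67) and endocrine (−3.98) lists, and with the authors' deposited log2 fold change in the other 5 (2.46 to 4.97). Percentiles were computed for the ratios as reported and not under the alternatives. The skeletal muscle median has no value with 1 FPKM in both libraries, which left 0 genes. By construction, the alternatives behind these moves shrink, enlarge or remove ratios near the floor, shift every ratio alike or set a stricter limit. Replicate variation could not be examined with 1 library per genotype.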

Other observations

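All tests, their bounds and the genes named in this part were chosen after the values were seen. Rgs5, a regulator of G protein signalling, was 32.9 FPKM in the control and 5.73 in the mutant. Kcnj8 and Abcc9, neighbouring genes on chromosome 6 for the subunits of one potassium channel, were 33.8 against 13.1 and 19.5 against 7.22. The matrix protein genes Sparcl1, Col8a1 and Fbln2 were 136.7 against 25.5, 11.1 against 1.84 and 26.5 against 10.6 FPKM. Aldh1b1, an aldehyde dehydrogenase, was 36.9 against 6.60. Rdh10, which starts retinoic acid synthesis, was 30.5 against 9.37, the opposite direction to Aldh1a2.

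The nicotinic receptor subunit genes Chrna3 and Chrnb4 were 0.663 FPKM in the control against 4.68 in the mutant, and 0.453 against 3.84. The muscarinic receptor gene Chrm2 was 1.22 against 11.7, and the homeobox gene Tlx2 was 3.14 against 16.8. Myocd, a coactivator of smooth muscle genes, was 0.739 against 10.6. The acute phase genes Saa1 and Saa2 were 0.467 against 5.29 and 0.199 against 6.11, and reads can be shared between these near-identical copies.

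Acinar genes were lower, and a candidate explanation is that the same acinar RNA was diluted by other tissue in the mutant pool. Dilution alone lowers every acinar gene by one factor. The log2 FPKM ratios of the 9 acinar genes ran from −6.35 for Cpa1 to −2.46 for Cel, a range of 3.89, above a bound of 2.44 set at 2 times the smallest change in the authors' deposited table. That bound does not measure how far single genes vary between pools, which was not measured. The range therefore decides nothing, and dilution and an effect of genotype cannot be told apart.

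Gut and hedgehog genes were higher, and 2 candidate explanations were weighed. With more gut wall in the mutant dissection, listed genes of nerves, smooth muscle and gut epithelium would have higher values, and by the sign of the ratio alone 19 of 21 (90.5%) did, with Des among the exceptions and with Fcgbp counted although it is under the rule of size. With more hedgehog signalling in the mutant bud, the listed pathway genes would be higher, and 100% of the 9 were. Both counts were made on the genes that form the pattern, and each genotype had 1 pool, so the explanations cannot be told apart and neither gains evidence from them.

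Skeletal muscle genes were higher, and a candidate explanation is skeletal muscle tissue in the mutant dissection. It needs the listed muscle genes to be higher together, and 7 of the 7 in the table were, with Actc1 at 17.8 FPKM in the mutant. The count was made on the genes that form the pattern, and with 1 pool per genotype dissection and genotype cannot be told apart.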
